A study of Mus musculus with 2 samples.

How the data were processed

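Total RNA from B16F10 cells, a mouse melanoma line that makes melanin, was measured on 2 single-colour Affymetrix arrays. The cells had been transfected with an expression plasmid for NRF3 or for GFP together with a puromycin resistance vector and selected with puromycin. Both populations were treated with forskolin for 5 days, per the labels. Forskolin activates adenylate cyclase and raises cellular cAMP. Each group had 1 array, and the labels name no separate cultures. The RNA was extracted with ISOGEN II, and biotin-labelled cRNA was prepared from 100.0 ng of it, per the labels' protocols.

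The deposited values are log2 expression values per probe set. They were made with Affymetrix Expression Console and the robust multi-array average (RMA), per the submitters' processing notes. The version, the background settings and the genome build are not given in the sources used here. RMA puts arrays on a common scale at the probe level. The medians of the 28846 deposited log2 values were 6.05 on the GFP array and 6.13 on the NRF3 array. The highest log2 values deposited were 19.8 and 19.7, and 288 and 279 rows lay above 16, the log2 limit of a 16-bit scanner reading. The deposited scale is therefore not the plain log2 of scanner brightness, and every fold below is a fold on that scale. Array data give no read depth. The precision is limited by the number of arrays, and with 1 array per group no standard error, interval or p-value can be given.

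Of the 28846 rows, 19572 carried exactly 1 gene symbol in the platform annotation supplied with the series and none carried several. The other 9274 rows were 6640 control rows and 2634 gene probe sets that are unnamed here. All 19572 named probe sets matched a RefSeq gene table (assembly GRCm38.p6) by gene number, and no symbol needed updating. The chromosome in the probe set's name and the one in that table were the same for 19458 of 19460 probe sets. The table was used only for names, chromosomes and gene order, and no coordinates are printed because the build of the array annotation is not stated. For the 55 genes with several probe sets, the one with the highest mean was used, which left 19505 genes. A gene was called detected when the brighter of its values reached 5.89, the median of all values of the named probe sets. This floor is a rule and not a measured background. Of the 5222 control rows whose names hold the word neg, 66.5% reached it, with medians of 6.12 on the GFP array and 6.37 on the NRF3 array. Some of these rows carry strong signal, up to 18.8 and 19.5, so they are no plain background either. A gene called detected near the floor is thus not shown to be expressed. The floor was met by 10162 genes, 52.1% of those named. The upper quartiles of the rows named neg were 7.52 on the GFP array and 7.85 on the NRF3 array. A difference with a value under these may depend on background, also where this is not repeated below.

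The comparison was the log2 value on the NRF3 array minus that on the GFP array. Genes were counted with a rule of size, at least 2-fold either way, which is not a test. For 29 gene lists, the median difference of the detected members was placed among the medians of 10000 random lists of the same size. The random lists were drawn from the detected genes and matched on mean level in 20 bins. A list was said to lie apart when its percentile was under 2.5 or over 97.5. Lists with fewer than 5 detected members got no percentile. Of the 701 list entries, 626 matched a named gene. Such a percentile describes these 2 arrays and says nothing of the spread between cultures. Among list members, at least 1.5-fold was used as the rule of size.

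The gene lists, the size rules, the rule for named genes and most of the alternatives were fixed before the data were examined. The genes named are Nfe2l3, the 12 detected genes with the largest and the 12 with the smallest difference, and up to 4 members of each list, the 2 highest and the 2 lowest. Predicted gene models and multigene families were not named but stayed in the counts. Tyr, Tyrp1, Dct, Pmel and Mitf were always named. Genes outside this rule are given where a count needed an example, and they were chosen after their values were seen.

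Detected genes on the autosomes and the X chromosome were also ordered along each chromosome and cut into 192 blocks of at least 50 neighbours. A block was said to lie apart when its median, relative to all detected genes, exceeded the 95th percentile of the largest block median in 1000 shuffled gene orders. Alternatives were other size rules and floors, subtraction of a lowess trend on mean level (span 0.3), median centring, quantile normalization, the mean over probe sets, and for lists the mean, unmatched random lists and the loss of the most extreme member, which is the one farthest from the list median. Subtracting block medians and leaving out chromosomes 1 and 8 were added after the data were seen, as was a comparison of the spread of differences between levels.

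The scripts were tested on simulated data, with the same 10162 genes for the gene and list steps and the 10156 genes in blocks for the block steps. Of 200 genes given a log2 difference of 2, 191 passed the 2-fold rule. All 20 lists of 30 genes shifted by 0.5 were placed apart, as was 1 of 20 unshifted lists. In simulated gene orders without a shift, 0 of 192 blocks lay apart, and 12 of 13 blocks of a chromosome shifted by 0.5 did. The simulated differences were independent between genes, with a standard deviation of 0.5. The real differences were wider, with a standard deviation of 0.69 over the named gene probe sets, and neighbouring genes differed together. The simulated shares may therefore be better than those in the real data. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.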

Results

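Gene expression was compared between B16F10 melanoma cells that stably expressed NRF3 and B16F10 cells that expressed GFP. NRF3, encoded by Nfe2l3, is a transcription factor of the cap'n'collar family that is anchored in the endoplasmic reticulum. Both populations had received forskolin for 5 days, so the comparison concerns NRF3 expression under forskolin and not the response to forskolin. The data were 2 arrays, 1 per group, each with 28846 values on the log2 RMA scale. There were no replicates, so no difference below has an error or a p-value, and each one compares these 2 RNA samples. Across the 10162 detected genes the values on both arrays were correlated with a Pearson r of 0.952, computed across genes, which are not independent replicates. The median difference of NRF3 minus GFP was -0.07, with quartiles of -0.55 and 0.39.

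Nfe2l3 (NCBI gene 18025, chromosome 6) was higher in the NRF3 cells. Its log2 value was 6.04 on the GFP array, close to the detection floor of 5.89 and under the median of 6.12 of the control rows named neg on that array, and 10.1 on the NRF3 array. The GFP value cannot be told from background, so the log2 difference of 4.11, or 17.2-fold, depends on that background and does not measure the size of the overexpression. The labels do not say which species' coding sequence the plasmid carried, and the probe set reads the mouse gene. Other members of the family and their partners differed less. Of 8 detected cap'n'collar and small MAF genes and Keap1, 1 was at least 1.5-fold higher, Maff, and none was as much lower. Maff lay at 5.10 on the GFP array and 6.12 on the NRF3 array, where the median of the rows named neg was 6.37, so neither value can be told from background. Nfe2l2, which encodes NRF2, differed by -0.46 and Bach2 by -0.27, and Keap1, the NRF2 repressor, by 0.39. The NRF3 value of Bach2, at 5.93, lay under the same median of 6.37, so it cannot be told from background either.

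In all, 686 detected genes were at least 2-fold higher in the NRF3 cells and 1122 were at least 2-fold lower. After quantile normalization of the 2 columns over the detected genes the counts were 876 higher and 910 lower. The size of the excess of lower genes at 2-fold thus depends on the scaling. Differences of at least 4-fold were found for 61 higher and 179 lower genes. Of the 1808 genes past the 2-fold rule, 107 of the higher ones had a GFP value under the floor and 179 of the lower ones an NRF3 value under it. By the medians of the rows named neg, 128 of the higher and 252 of the lower genes had such a dim value. Their folds depend on background. Of the common reference genes, 13 of 13 detected were within 1.5-fold. Gapdh differed by -0.04, Actb by -0.23, Hprt by 0.56 and Sdha by -0.58.

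**Figure D1:**
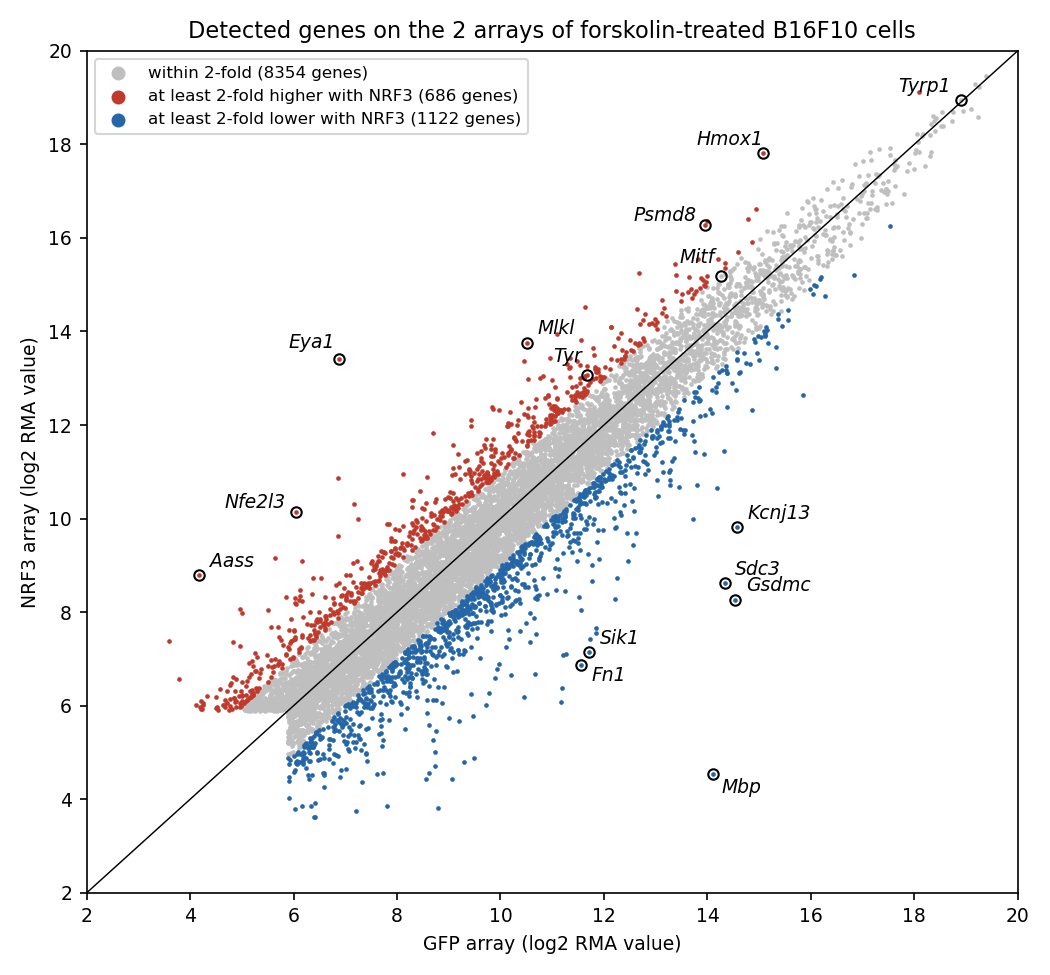
Log2 RMA value of each detected gene on the GFP array (horizontal axis) and the NRF3 array (vertical axis). The line marks equal values, red and blue points pass the 2-fold rule, and open circles mark a selection of the named genes. Nfe2l3 lies at 6.04 on the GFP axis and 10.1 on the NRF3 axis, Tyrp1 lies on the line, and Mbp lies farthest below it.

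The largest difference toward higher values in the NRF3 cells was that of Eya1, a transcriptional co-activator and phosphatase of development, with log2 values of 6.87 in GFP and 13.4 in NRF3 cells, a 93.0-fold difference. Aass, the bifunctional enzyme that starts lysine breakdown, was higher by 4.62 on the log2 scale. Sema6d, a transmembrane semaphorin, was higher by 4.02 and Pde8a, a cAMP phosphodiesterase, by 3.79. The G protein subunit gene Gng11 was higher by 3.51. Mlkl, the effector of necroptosis, was higher by 3.25, Ell, a transcription elongation factor, by 3.14 and Atmin by 3.13. Cbr1, a carbonyl reductase, was higher by 3.11, Serpinb8 by 2.98 and Uchl1, a ubiquitin hydrolase, by 2.93. For Aass, Pde8a, Gng11, Cbr1 and Serpinb8 the GFP value lay under the floor, so the size of their differences depends on background. That of Uchl1, at 6.17, lay just above the median of the rows named neg. The GFP values of Eya1, Sema6d and Ell lay farther above that median but under the upper quartile of those rows, 7.52. The size of their differences may therefore depend on background too. Ell, Mlkl and Atmin all lie on chromosome 8, whose genes were higher as a whole.

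The lowest difference was that of Mbp, the gene of myelin basic protein, at -9.57, from 14.1 in GFP to 4.54 in NRF3 cells. Gsdmc, which encodes a pore-forming gasdermin, differed by -6.27 and Sdc3, a heparan sulfate proteoglycan, by -5.72. Wfdc3 differed by -5.10, Cda, which encodes cytidine deaminase, by -4.99 and Pltp, a phospholipid transfer protein, by -4.81. Kcnj13, an inward rectifier potassium channel, differed by -4.77 and Fn1, the fibronectin gene, by -4.68. The microtubule-associated Map1a differed by -4.64 and the small heat shock gene Hspb8 by -4.61. Sik1, a kinase gene induced by cAMP, differed by -4.57, and Fam178b by -4.49. The NRF3 values of Mbp, Cda, Map1a, Hspb8 and Fam178b lay under the floor. That of Wfdc3, at 6.07, lay under the median of the rows named neg on that array, 6.37, and that of Pltp, at 6.38, level with it. The size of all these differences depends on background. Fn1, at 6.88, and Sik1, at 7.15, had NRF3 values above that median but under the upper quartile of those rows, 7.85. The size of their differences may depend on background too.

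Proteasome genes had the highest median difference of the 25 gene lists with a percentile. Of 35 detected subunit and assembly genes, 26 were at least 1.5-fold higher in the NRF3 cells and 0 were that much lower. The median log2 difference was 0.90, or 1.86-fold, and none of 10000 random lists matched on level reached it. The largest differences were those of Psmd8, at 2.33, Psma5, at 2.22, Psmd4, at 1.85, and Psmc2, at 1.60. They came from the core particle and the regulatory particle alike. Pomp, the proteasome maturation protein, was higher by 0.61. The assembly chaperone genes Psmg1 and Psmg2 lay at -0.07 each, and after median centring or quantile normalization they lay marginally above 0.

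Autophagy genes were also higher as a list. Of 34 detected, 16 were at least 1.5-fold higher and 2 as much lower, with a median of 0.56 that none of 10000 random lists reached. Map1lc3b, which encodes the autophagosome protein LC3B, was higher by 1.98, and the cargo receptor genes Nbr1 and Calcoco1 by 1.33 and 1.30. The kinase gene Ulk2 was higher by 1.28 and Gabarapl2 by 1.17. Atg2a and Atg4d were lower by 0.70 and 0.68. The lysosome list had a median of 0.34, at percentile 99.7, with 8 of 28 members higher and 5 lower. Mcoln1, a lysosomal calcium channel gene, was higher by 1.96, Gla by 1.95, Ctsl by 1.75 and Cln3 by 1.74. Ctsh, at -3.19, and Psap, at -1.49, lay on the other side. Of the 8 higher members, 3 lie on chromosome 8, Mcoln1, Atp6v0d1 and Galns. With the median of neighbouring genes subtracted, the lysosome list lay at percentile 45.0 and no longer lay apart. With chromosomes 1 and 8 left out its median turned to -0.10, at percentile 42.1. The macropinocytosis and early endocytosis list had a median of 0.27 at percentile 98.4. Only 4 of its 27 members were 1.5-fold higher and 4 were lower, among them Rhou at 1.39, Rabgef1 at 0.95 and Sdc1 at -1.63. Its percentile was 88.2 when the mean replaced the median and 95.8 with the median of neighbouring genes subtracted, so this list did not hold apart.

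Genes of cholesterol synthesis were higher, with a median of 0.57 over 20 detected members, a value reached by 2 of 10000 random lists. Of these, 10 were at least 1.5-fold higher and 1 as much lower. Cyp51 was higher by 1.95, Msmo1 by 1.86, Fdps, the farnesyl diphosphate synthase, by 1.73, and Insig1 by 1.42. Hsd17b7 differed by -1.55 and Idi1 by -0.38. The fatty acid synthesis list did not lie apart, with a median of -0.28 over 13 members at percentile 19.1. Its highest members were Elovl5, at 0.74, and Elovl1, at 0.63, and its lowest Elovl6, at -1.69, and Fasn, the fatty acid synthase, at -1.25.

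Antioxidant genes of the kind NRF2 controls had a median of 0.37 over 24 members, at percentile 99.8, but members went both ways, 8 higher and 4 lower by 1.5-fold. Slc7a11, the cystine transporter gene, was higher by 2.85, Hmox1, heme oxygenase, by 2.72, Blvrb by 2.48 and Gclm, of glutathione synthesis, by 2.38. Gsta4 differed by -3.44, Ephx1 by -1.67, Me1 by -1.06 and Txnrd1 by -0.79. The NRF3 value of Gsta4, at 5.26, lay under the floor, so the size of its difference depends on background. Nqo1, a widely used NRF2 target, differed by -0.19. Its values, 7.45 in GFP and 7.26 in NRF3 cells, lay under the upper quartiles of the rows named neg, 7.52 and 7.85. The small difference of Nqo1 may therefore reflect background. The unfolded protein and integrated stress response list had a median of 0.56 over 28 members, reached by 1 of 10000 random lists, with 11 members 1.5-fold higher and 2 lower. Vldlr was higher by 1.91, from a GFP value of 5.94 that cannot be told from background, Herpud1, of endoplasmic reticulum-associated degradation, by 1.73, Atf5 by 1.65 and Dnajb9 by 1.47. Ddit3, which encodes CHOP, and Trib3 lay at -0.89 and -0.85. The heat shock list had a median of 0.44 over 11 members at percentile 97.7, but a mean of -0.01, with Hspb8 at -4.61, a size set by background, among them. It lay at percentile 62.2 by the mean and 91.0 after subtraction of the intensity trend, so it did not hold apart. Dnajb1 was higher by 1.26 and Hspa4l by 1.06, and Hspd1 lay at -0.80.

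Proliferation genes were lower in the NRF3 cells. Of 32 detected, 25 were at least 1.5-fold lower and 0 were that much higher, and the median of -0.90 lay below all 10000 random lists. Top2a, topoisomerase II alpha, differed by -1.91, the mitotic kinesin gene Kif11 by -1.59, the kinase gene Aurkb by -1.55 and Rrm2 by -1.32. Mcm2 lay at -1.19, Mcm5 at -1.01 and Cdt1 at -0.27. Ccna2, at 0.01, and Tyms, at -0.18, differed least. The p53 target list had a median of -0.31 at percentile 13.4, with 7 of 14 members lower. Phlda3 differed by -1.94 and Cdkn1a, which encodes p21, by -1.14, while Trp53inp1 and Plk2 were higher by 1.71 and 1.19. The NRF3 value of Phlda3, at 7.15, and the GFP value of Plk2, at 6.60, lay under the upper quartiles of the rows named neg, 7.85 and 7.52. The size of these 2 differences may depend on background. The percentile of the p53 list depended on the members used. Without Trp53inp1, the member farthest from the list median, it was 0.75 with a median of -0.64, but with chromosomes 1 and 8 left out it was 77.4 with a median of 0.09, and with the floor at the 75th percentile of values 65.6.

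Matrix and adhesion genes were lower, with a median of -0.61 over 18 detected members at percentile 0.32, of which 10 were 1.5-fold lower and 3 higher. After Fn1 the largest differences were those of the integrin genes Itga6, at -2.37, and Itga4, at -2.17. Itga5, the fibronectin receptor alpha subunit, was higher by 1.42. With the floor at the 75th percentile of values this list lay at percentile 2.92, just inside the central range. Oxidative phosphorylation genes had a median of -0.38 over 34 members at percentile 0.83, with Ndufs7 at -1.68 and Ndufs1 at -1.67. Ndufb5 was higher by 0.95 and Cox4i1 by 0.87. With the median of neighbouring genes subtracted this list lay at percentile 8.14 and no longer apart.

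The pigment gene list did not lie apart. The 17 melanin synthesis and melanosome genes had a median of -0.07 at percentile 50.3, with 4 at least 1.5-fold higher and 2 lower. Tyr, which encodes tyrosinase, the rate-limiting enzyme of melanin synthesis, was 2.66-fold higher, with log2 values of 11.7 in GFP and 13.1 in NRF3 cells. The transporter genes Oca2 and Slc24a4 were higher by 2.83 and 2.47. Tyrp1 and Pmel, both above 18 on each array, differed by 0.05 and 0.12, and Dct by -0.25. Of the 17 members, 8 lay above 16 on both arrays. Differences were smaller at the top of the scale, with an interquartile range of 0.27 over the 25 detected genes with a mean level above 18. It was 0.80 over the 140 with a mean above 16 and up to 18, and 0.94 over the 9997 with a mean up to 16. The small differences of Tyrp1 and Pmel therefore do not show equal expression. Trpm1, a melanocyte channel gene, and Mfsd12 lay at -2.54 and -2.14. The GFP value of Slc24a4, at 5.84, and the NRF3 value of Mfsd12, at 5.70, lay under the floor, so the size of their differences depends on background. Mitf, the master regulator of the melanocyte lineage, was 1.90-fold higher, from 14.3 to 15.2. The lineage regulator list had a median of 0.27 over 15 members at percentile 95.7, with Met highest at 2.88 and Bcl2 lowest at -2.18. Its percentile was 99.0 with the floor at the 75th percentile of values, 86.4 without Met and 55.1 without a floor, so it did not hold apart. Sox10 and Cdk2 differed by -0.49 and -0.65. Of 29 melanosome biogenesis and transport genes 8 were higher and 7 lower, with a median of 0.17 at percentile 94.4. Sytl2 was higher by 1.88 and Ap1g1 by 1.25, while Mlph and Rab17, which act in melanosome transport, lay at -1.73 and -1.64. The GFP value of Sytl2, at 7.22, lay under the upper quartile of the rows named neg, 7.52, so the size of its difference may depend on background. Mlph and Rab17 lie on chromosome 1, whose genes were lower as a whole, and Ap1g1 on chromosome 8. Of 12 detected cAMP-responsive genes 3 were higher and 2 lower, with a median of 0.23 at percentile 88.7. By the mean, -0.11, the percentile was 47.65, so this list did not lie apart. Nr4a3 was higher by 2.49 and Ppargc1a by 1.01, and Atf3 lay at -2.14 beside Sik1.

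**Figure D2:**
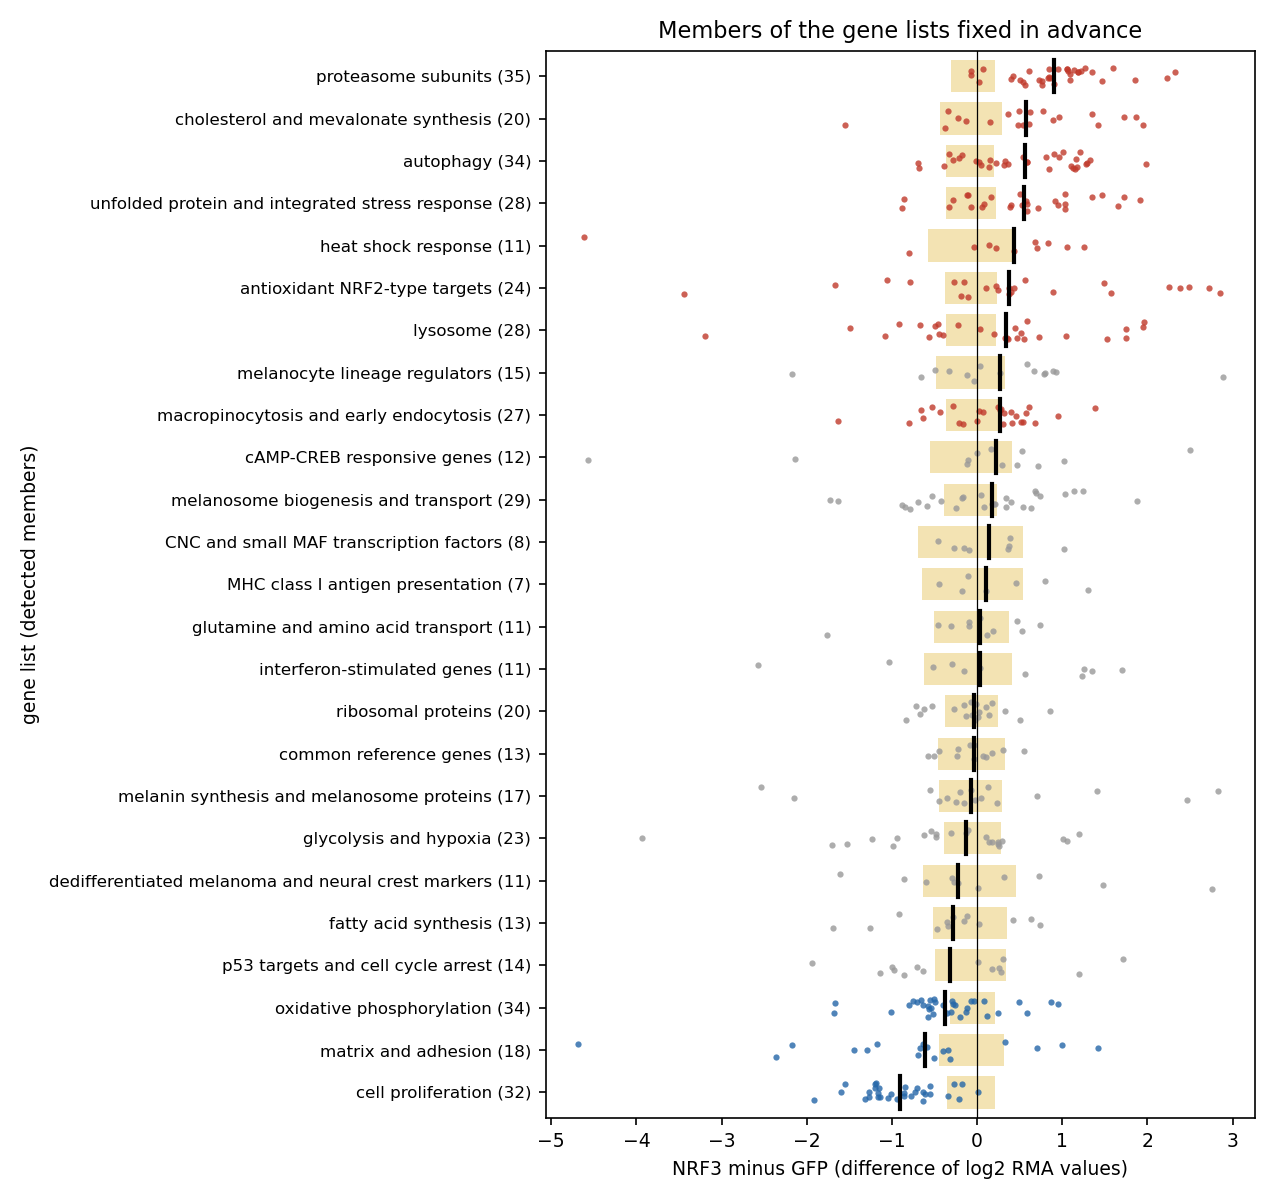
Difference of log2 RMA values, NRF3 minus GFP (horizontal axis), of each detected member (points) of the 25 gene lists with a percentile (vertical axis); black bars are list medians and shaded boxes span the central 95% of medians of random lists matched on level. Red lists lie above and blue lists below the boxes, with medians from 0.90 for proteasome subunits to -0.90 for cell proliferation.

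The other lists lay within the range of random lists. They were interferon-stimulated genes (percentile 67.4, Ifit3 at 1.70, Xaf1 at -2.57), class I antigen presentation (71.3, H2-K1 at 1.30, B2m at -0.45), glycolysis and hypoxia (30.9, Egln1 at 1.20, Ndrg1 at -3.93), amino acid transport (66.4, Slc3a2 at 0.74, Slc1a4 at -1.77), ribosomal proteins (55.3, Rpl5 at 0.86, Rpl37a at -0.83) and dedifferentiated melanoma markers (30.5, Sox9 at 2.75, Axl at -1.60). Of these, Ifit3 had a GFP value, and Xaf1 and Axl an NRF3 value, under the median of the rows named neg, so the size of their differences depends on background. The GFP values of Sox9, at 7.24, and H2-K1, at 7.31, lay above that median but under the upper quartile of those rows, 7.52. The size of their differences may depend on background too. The common reference genes lay at percentile 55.0 and the cap'n'collar list at 73.2. Only 4 Wnt target genes were detected, Axin2 at 1.34, Dkk3 at 0.41, Znrf3 at -0.29 and Myc at -3.50. The GFP value of Axin2, at 6.39, also lay under the upper quartile of 7.52. Of 25 lists with a percentile, 8 lay above and 3 below the central range, against 1.25 outside it that random lists would give. Random lists draw their genes singly, whereas members of a real list can vary together between cultures. The comparison with 1.25 is therefore no test of NRF3. None of the named markers of leukocytes (13 genes), of fibroblasts and endothelium (11) or of epithelium (12) was detected. The brightest were Lyz2 at 5.43, Col6a3 at 5.73 and Krt10 at 5.42, all under the floor.

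Differences also followed the chromosomes. The 549 detected genes of chromosome 8 were higher in the NRF3 cells with a median of 0.56, and 146 of them passed the 2-fold rule upward and 28 downward. The 552 detected genes of chromosome 1 were lower with a median of -0.51, and 129 passed the rule downward and 8 upward. On the other chromosomes the medians ran from -0.28 on chromosome 19 to 0.23 on chromosome 7. Of the 192 blocks of neighbouring genes, 20 lay beyond the bound of 0.43 set by shuffled gene orders, 12 higher and 8 lower. They included 8 of the 10 blocks of chromosome 8 and 6 of the 11 of chromosome 1. With block medians subtracted, the proteasome, autophagy, cholesterol, antioxidant, unfolded protein, heat shock, proliferation and matrix lists still lay apart in the same direction.

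**Figure D3:**
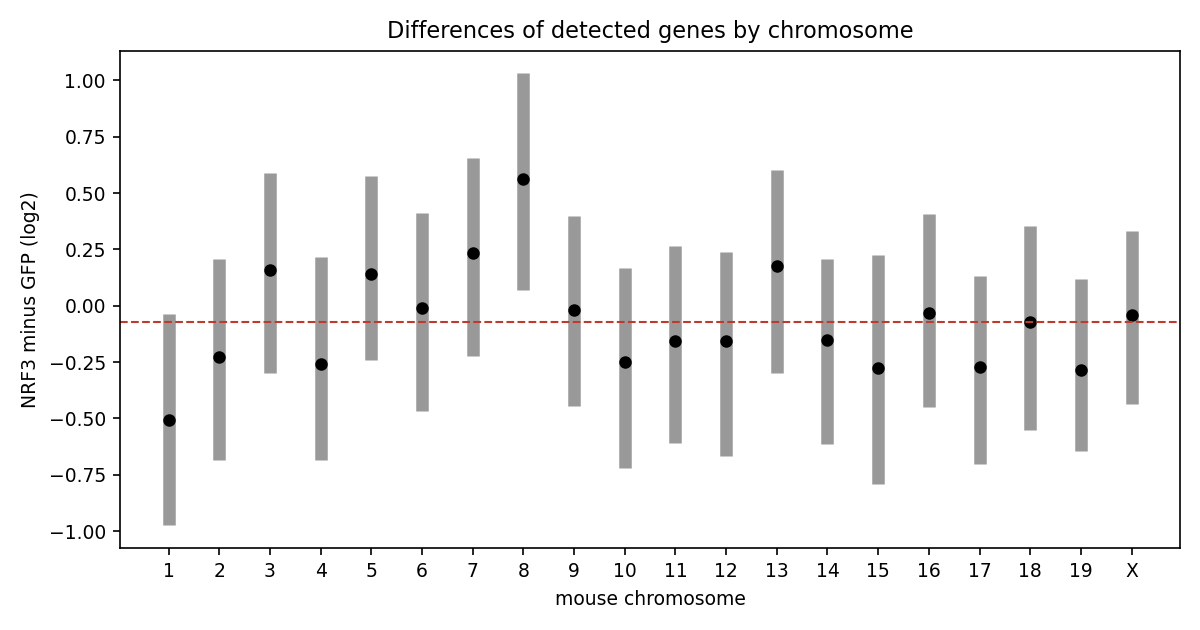
Median (points) and quartiles (grey bars) of the log2 difference NRF3 minus GFP of the detected genes of each mouse chromosome; the dashed line is the median of all detected genes, -0.07. Chromosome 8 lies highest with a median of 0.56 and chromosome 1 lowest with -0.51.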

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

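The rows below lie outside the comparison of named genes and were looked at only after the named genes. Of 2634 gene probe sets without a gene name, 1126 were detected, and 61 of these were at least 2-fold higher on the NRF3 array than on the GFP array while 113 were at least 2-fold lower. These are 5.42% and 10.0% of the detected unnamed probe sets, beside 6.75% and 11.04% of the detected named genes. The 5222 control rows whose names hold the word neg had a median difference, NRF3 minus GFP, of 0.27 on the log2 scale, against 0.01 for the named gene probe sets and for the 1324 control rows named pos. Their median levels, 6.12 on the GFP array and 6.37 on the NRF3 array, lie above the detection floor of 5.89. The median differences were -0.11 for 63 ERCC rows, 0 for 23 background probe bins and -0.02 for 4 labelling controls. Only 7 of the ERCC rows reached the floor. The median of 0 hides differences between the bins, which ran from -0.12 to 1.05. Bins with low GC numbers in their names were mostly higher on the NRF3 array, GC03 by 1.05 and GC07 by 0.35, though GC06 lay at -0.11. GC22 and GC24 lay at -0.08 and -0.12. The 4 hybridization controls, which are added to the sample after labelling, were all higher on the NRF3 array, by 0.18 to 0.38.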

How the results depend on the processing

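No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. The count of genes at least 2-fold higher, 686, became 1728 at 1.5-fold, 168 at 3-fold and 401 with the floor at the 75th percentile of values, and the count of lower genes, 1122, became 2396, 371 and 588. The last setting considers 5328 genes, and in each of these settings more genes were lower than higher. The other 16 values of these counts stayed within 1.5 times. Nfe2l3 stayed over 2-fold higher in all 5 alternatives, and of 640 values of 128 other named genes 609 kept their direction and side of the 2-fold rule; none that passed the rule changed direction. Of 222 list percentiles under an alternative, 206 stayed on the same side. By the mean instead of the median the percentile was 95.9 for lysosome, 88.2 for macropinocytosis and 62.2 for heat shock. Without a floor it was 92.5 for lysosome. With the floor at the 75th percentile it was 97.4 for lysosome, 77.8 for heat shock, 2.92 for matrix and adhesion, 99.0 for lineage regulators and 97.7 for melanosome transport. After subtraction of the intensity trend heat shock lay at 91.0, and without its most extreme member the p53 list lay at 0.745 but lineage regulators at 86.4. Without a floor lineage regulators lay at 55.1, and the p53 list had a median above 0 and lay at 65.6 with the floor at the 75th percentile. In alternatives chosen after seeing the data, subtracting block medians gave 45.0 for lysosome, 95.8 for macropinocytosis and 8.14 for oxidative phosphorylation. Leaving out chromosomes 1 and 8 gave 42.1 for lysosome, whose median turned from 0.34 to -0.10, 99.9 for lineage regulators and 77.4 for the p53 list, again with a median above 0. The proteasome, autophagy, cholesterol, antioxidant, unfolded protein and proliferation lists lay apart in all 9 alternatives. Quantile normalization moved the median of detected genes by 0.10, and list percentiles were not run under it. The cause of the other changes was not tested.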

Other observations

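The 12 gene families in this and the next paragraph were chosen after the data were seen, as were the removal of members shared with other lists and the reading of left-out genes used below. Factors of p97-dependent and endoplasmic reticulum-associated degradation, which deliver ubiquitinated proteins to the proteasome, had a median difference of 0.57 over 24 detected members, reached by 1 of 10000 random lists. Of these 11 were at least 1.5-fold higher and 0 as much lower, among them Ubxn8 at 1.90, Faf2 at 1.52, Vcp, which encodes p97, at 0.98, and its cofactor genes Nploc4 at 0.82 and Ufd1 at 0.79. The 21 that no other list holds lay at percentile 99.97. Subunits of the vacuolar proton pump, which acidifies lysosomes and melanosomes, had a median of 0.47 over 16 members at percentile 99.5, 6 of them higher and 1 lower by 1.5-fold, with Atp6v0d1 at 1.52, Atp6v1a at 1.04 and Atp6v0e2 at -0.71. Without the 3 that the lysosome list also holds, they lay at percentile 94.8 and not apart. RAB GTPases lay at the edge with a median of 0.18 at percentile 97.6, Rab13 at 1.37 and Rab4a at 1.10 against Rab17 at -1.64, and at 96.2 without the 9 members of lists reported above.

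Replication and repair genes had a median of -0.41 over 55 members at percentile 0.28, with 22 lower, 3 higher and 30 within 1.5-fold. Rpa3 lay at -1.34, Rfc3 at -1.26 and Pola2 at -1.22, and on the other side Gins4 at 1.22, Orc6 at 0.94 and Fancl at 0.93. The proliferation list also holds 5 of them, Mcm2 to Mcm6, and the other 50 lay at percentile 1.01. Kinesins had a median of -0.57 over 25 members at percentile 0.40, with 12 lower and 0 higher, but the 21 that no other list holds lay at 3.44 and not apart. Splicing factors had a median of -0.37 over 58 members at percentile 0.40, with 18 lower, 3 higher and 37 within 1.5-fold. Prpf39 lay at -2.10 and Hnrnpd at -1.71, and Snrpb2 at 1.30 and Sf3b3 at 1.08. Mitochondrial ribosomal protein genes had a median of -0.31 at percentile 0.76 but lay at 6.5 with block medians subtracted. Ubiquitin-conjugating enzymes (percentile 96.7), the cytosolic chaperonin (64.9), nucleoporins (66.9), cytosolic tRNA synthetases (19.1) and histones (20.4) lay within the range of random lists.

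Differences clustered along chromosomes, with 20 of 192 blocks of neighbouring genes beyond the bound from shuffled orders, most of them on chromosomes 8 and 1. An intensity trend between the arrays would remove the blocks once subtracted, but 18 stayed. After subtraction of a trend on local gene density, used as a stand-in for GC content, 18 also stayed. GC content was not itself measured, so the stand-in cannot exclude a difference between the arrays that depends on GC content. Background probe bins with low GC numbers were mostly higher on the NRF3 array, GC03 by 1.05 and GC07 by 0.35, with GC06 at -0.11 and GC24 at -0.12. A bias of composition thus stays open. When blocks were called on the mean of every other gene, 6 lay higher and 1 lower. Of the 199 genes left out of these calls, 87.4% lay on their block's side of the median of all detected genes. Without any 1 block this share was 85.6% or more. A changed minority would be expected to give at most 75%, provided that the other genes split evenly about the median of all detected genes. In the 6 higher blocks the share was 88.5%, so under that condition a changed minority does not account for them as a set. In the 1 lower block the share was 80%. That is close to the limit and rests on the genes of 1 block, so a changed minority is left open there. A candidate explanation is a difference in chromosome copy number between the 2 stable populations, which the 20 blocks are consistent with and which no DNA measurement here tests. Regulation of whole regions by NRF3 remains open and was not tested. Single genes on these chromosomes may owe part of their difference to their place. Examples are Hmox1, Mlkl, Ell, Map1lc3b and Herpud1 on chromosome 8 and Mlph, Rab17, Fn1, Bcl2 and Phlda3 on chromosome 1. Smaller shifts were seen elsewhere. On chromosome 7, 68.0% of the detected genes lay above the median of all detected genes, so genes there, such as Tyr and Oca2, may be affected too.

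The proteasome list had a median of 0.90. Place on shifted chromosomes does not account for it, since the median was 0.94 with block medians subtracted. Nor does an intensity trend, since it was 0.94 with the trend subtracted, and both medians lay above all random lists. Each subtraction also moved the median of all detected genes up by 0.07, so 0.94 does not show a larger difference than 0.90. What stays open is whether the difference goes with NRF3 or with another difference between the cell populations or cultures, because 1 NRF3 population was measured.

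The proliferation list had a median of -0.90. With block medians subtracted its median was -0.78 and with the intensity trend subtracted -0.85, both below all random lists, so neither explanation accounts for it. Each subtraction moved the median of all detected genes up by 0.07, so these medians and -0.90 have different centres. With 1 NRF3 population measured, NRF3, clonal growth rate and culture density at harvest cannot be told apart.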
